A study of Mus musculus with 12 samples.

How the data were processed

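RNA was measured by single-read sequencing of cDNA from microglia, the resident macrophages of the brain, sorted by flow cytometry from brains of C57BL/6J mice. The 12 libraries fall into 3 genotypes of 4 libraries each, grouped by the genotype label alone: wild type (WT), mice with 1 copy of a CreERT2 cassette inserted at the Hexb locus (HET), and mice with 2 copies (HOM). Libraries are named by genotype and a replicate number in accession order. The library number in the labels is 1, 2, 7 and 10 for WT 1 to 4, 4, 6, 9 and 11 for HET 1 to 4, and 3, 5, 8 and 12 for HOM 1 to 4. CreERT2 is a Cre recombinase joined to a mutated ligand-binding domain of the human oestrogen receptor, which lets Cre enter the nucleus when tamoxifen is given. Hexb encodes the beta subunit of the lysosomal enzyme beta-hexosaminidase. Total RNA was purified on spin columns and turned into cDNA with the SMARTer ultra low input kit, amplified, tagmented with Nextera XT and sequenced on an Illumina NextSeq, per the labels' protocols. This kit amplifies very small amounts of RNA and does not mark the strand a read came from. PCR copies of one molecule cannot be recognised in such libraries, so counts of reads are not counts of molecules.

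The deposited table holds whole-number read counts per gene symbol for 55341 genes in 12 columns, with gene coordinates, strand and summed exon length, as its header shows. Reads were aligned with STAR 2.7.2a to mouse genome build GRCm38.p6 and counted per gene with featureCounts 1.6.2, per the submitters' processing notes. The same notes name limma for later statistics, without a version. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Of the 55341 genes, 55215 have the coordinates of GENCODE release M21, which uses GRCm38, and coordinates are printed on that build. In the deposited counts, 13 gene names had been turned into dates, and these genes were kept in the totals under the names as deposited. No library carried a second column, and 0 columns of values were left unused. A read that falls in exons of 2 overlapping genes can be lost or assigned to either, so values of overlapping genes carry that limit.

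All values printed here were computed from the deposited counts. Genes were kept by filterByExpr in edgeR 4.0.16, which left 14641, and libraries were scaled with TMM factors, which correct library size for differences in composition. Normalised read counts are given as CPM with those factors. The main test was edgeR's quasi-likelihood F-test over all 12 libraries with 1 term per genotype, 9 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A second fit used the number of knock-in alleles (0, 1 or 2) as a numeric term. Hexb was reported first because its level checks the genotype labels. For Hexb, Gfm2 and Esr1, an exact two-sided permutation test of mean CPM was added, whose 70 assignments of 8 libraries to groups of 4 allow no p below 0.0286. List means per library are means of log2 CPM over tested members with a prior count of 2. Errors are standard deviations (SD) for values per group and standard errors (SE) for log2 fold changes.

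Gene lists were tested with camera from limma 3.58.1, with the correlation between genes preset at 0.01 as the main call. Beside it stand camera with a correlation estimated from the data and fry, which asks whether the genes of a list move, on balance, in one direction. Adjustment was over the lists of each comparison. The lists were homeostatic microglia genes, disease-associated microglia genes, interferon-stimulated genes, antigen presentation genes, lysosomal hydrolases and cofactors, lysosomal membrane and acidification genes, glycosphingolipid synthesis genes, inflammatory cytokine and NF-kB genes, immediate early and heat shock genes, unfolded protein and amino acid stress genes, sterol synthesis genes, proliferation genes and complement genes. Marker lists covered border-associated macrophages, monocytes and dendritic cells, neutrophils, lymphocytes, erythroid cells, neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells, and choroid plexus and ependyma. Mitochondrially encoded, ribosomal protein and sex-linked genes made up the remaining lists. Ctsb, Ctsd and Ctsl are in both the disease-associated and the lysosomal hydrolase list, and Cd63 and Gpnmb are in both the disease-associated and the lysosomal membrane list.

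The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, Hexb, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM, and, where fewer than 10 genes pass, the 5 smallest unadjusted p-values in each direction. It also takes up to 4 members of each list past the threshold or else the 2 members with the highest mean CPM, the 3 nearest tested genes on each side of Hexb, and Esr1, because CreERT2 carries part of the human oestrogen receptor. Any other gene named was chosen after its values were seen.

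Total counts ranged from 24755542 to 37019181 per library. The biological coefficient of variation was 0.209. Data were simulated 3 times over 14641 genes from the mean CPM and the library sizes of all 12 libraries, with changes put into HOM. The spread of each gene was taken from edgeR's own estimate. In HOM against WT, edgeR found 8.67% of genes changed by 1.25-fold, 52.0% at 1.5-fold, 80.0% at 2-fold and 93.3% at 3-fold, with 26 false calls among 377. Among simulated genes with at least 10 CPM, the shares were 12.7%, 76.5%, 99.0% and 100.0%. DESeq2 1.42.0 made 87 false calls among 461 in the same simulated data, and limma-voom made 18 among 359. Because the spread came from edgeR, these data may suit edgeR better than the other tools. A list of 25 genes shifted by 1.15-fold was called in 3 of 3 simulations by camera with the preset and with the estimated correlation, and the unshifted lists were called in 0. Simulated genes varied independently of each other, so these simulations cannot test whether the preset correlation suits the real lists. The correlation estimated from the data was 0.47 for interferon-stimulated genes in HOM against WT.

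Alternatives fixed beforehand were median-ratio (RLE) size factors, library size without a composition factor, no low-count filter, a filter of 1 CPM in at least 4 libraries, DESeq2, limma-voom, edgeR with robust estimation, a fit of only the groups compared, the library number or sex-linked expression as a covariate, leaving out each library in turn, and other windows around Hexb. Added after the data were examined were fits without WT libraries 1 and 2, fits within library numbers 1 to 7 and 8 to 12, neighbour tests without Gfm2, and fold-change comparisons without Hexb, Gfm2 and Esr1. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not used here, so sequence from the cassette itself was not analysed here.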

Results

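Gene expression was measured in 4 WT, 4 HET and 4 HOM libraries of sorted brain microglia. The series compares microglia that carry 0, 1 or 2 copies of a Hexb-CreERT2 knock-in allele, a driver line for tamoxifen-inducible recombination in microglia. Total counts were 25715705, 25287980, 35360797 and 24755542 in the WT libraries, 30309709, 28210137, 37019181 and 31119351 in HET and 35326469, 31448490, 33322477 and 27145355 in HOM. Each library had a count for 18905 to 21199 genes. The most abundant transcripts in WT were those of microglia and their lysosomes: Cst3, a cysteine protease inhibitor, at 32318 ± 1382 CPM, Csf1r, the receptor for the growth factor that keeps microglia alive, at 18551 ± 698 CPM, Hexb, the fractalkine receptor Cx3cr1 at 11324 ± 436 CPM, and the lysosomal protease Ctsd at 11084 ± 532 CPM (SD, n = 4). All mitochondrially encoded genes together took 0.288% to 0.413% of counts and ribosomal protein genes 0.351% to 0.510%. Pairs of libraries of a genotype differed with a chi-square of 12.2 to 37.0 per degree of freedom against counting noise alone. Amplified libraries of a single RNA would exceed that noise as well. The titles give each library its own second number but the labels do not say what separates the libraries of a genotype, so p-values measure the spread between these samples.

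The libraries also split by sex-linked transcripts. Library numbers 1 to 7 had 6385 to 10974 counts of Xist, the RNA that silences an X chromosome, and at most 6 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Library numbers 8 to 12 had 3861 to 6916 Y-linked counts and at most 1 Xist count. The first set holds 3 WT, 2 HET and 2 HOM libraries and the second 1 WT, 2 HET and 2 HOM, so this split and the library order coincide. On the first principal component of log2 CPM, with 14.9% of the variance, WT 1 and WT 2 lay at -33.2 and -57.8 and the other 10 libraries between -5.67 and 24.5. Library numbers 1 to 7 lay at or below 2.34 (WT 3) and numbers 8 to 12 at or above 15.5 (HET 3). This component therefore separated the sets with Xist and with Y-linked counts without overlap.

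Hexb (chromosome 13, 97176331 to 97198357, minus strand) followed the genotype label in every library. It stood at 17959 ± 603 CPM in WT, 9589 ± 379 CPM in HET and 418 ± 90.7 CPM in HOM (SD, n = 4 each). HET libraries therefore held 53.4% ± 2.11 of the WT mean and HOM libraries 2.33% ± 0.51. By mean level Hexb ranked 3 among all genes in WT, 6 in HET and 317 in HOM. Single libraries ranged from 17173 to 18588 CPM in WT, 9279 to 10114 CPM in HET and 326 to 497 CPM in HOM, with no overlap.

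**Figure D1:**
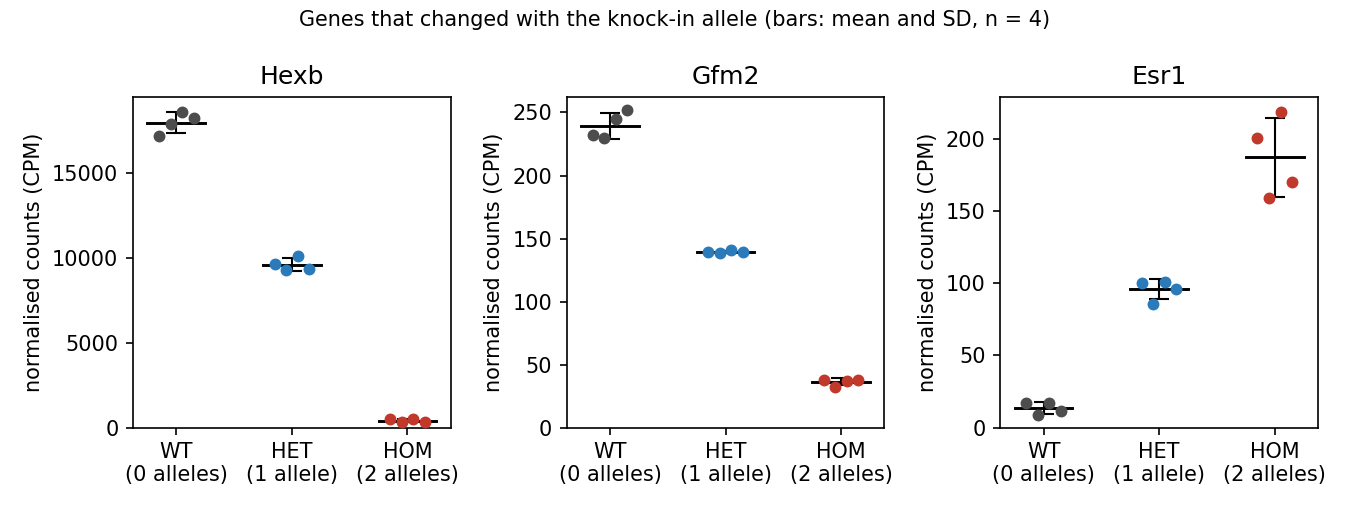
Normalised read counts (CPM, vertical axis) of Hexb, Gfm2 and Esr1 in each of the 12 libraries by genotype (0, 1 or 2 knock-in alleles, horizontal axis); points are libraries, horizontal lines the mean and bars the SD of 4. Hexb and Gfm2 step down and Esr1 steps up with each allele, and the 3 genotypes do not overlap for any of the 3 genes.

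The comparison of HOM with WT asks how microglia with both Hexb alleles carrying the cassette differ from microglia with none. Hexb fell by 5.43 on the log2 scale (SE 0.12, adjusted p = 5.38e-14 by edgeR). Gfm2, a mitochondrial translation factor whose gene overlaps the 3' end of Hexb on the opposite strand, fell from 239 ± 10.6 to 36.2 ± 2.78 CPM, a log2 fold change of -2.72 (SE 0.07, adjusted p = 3.38e-13 by edgeR). Esr1, the oestrogen receptor alpha gene (chromosome 10, 4611593 to 5005614, plus strand), rose from 13.5 ± 4.14 to 187 ± 27.5 CPM, a log2 fold change of 3.78 (SE 0.18, adjusted p = 1.89e-09 by edgeR). Part of the human counterpart of Esr1 is built into CreERT2, and the deposited counts do not separate reads of the cassette from reads of Esr1. Each of these 3 genes separated all 4 HOM from all 4 WT libraries, with an exact two-sided permutation p of 0.0286, the smallest that 70 assignments allow. Within library numbers 1 to 7, Hexb, Gfm2 and Esr1 differed by -5.39, -2.75 and 3.66, all past edgeR's threshold. Within 8 to 12 they differed by -5.46, -2.74 and 4.05, where the 1 WT library was assumed to vary like the HET and HOM libraries.

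These 3 were the only genes of 14641 past the threshold in HOM against WT, 1 up and 2 down, and 544 genes had an unadjusted p under 0.05 where chance alone would give 732. The next gene was Sdc3, which encodes the heparan sulfate proteoglycan syndecan-3, at 94.3 ± 7.30 CPM in WT and 129 ± 7.14 CPM in HOM (log2 0.45, SE 0.08, adjusted p = 0.236 by edgeR). Other genes with small unadjusted p-values and higher means in HOM were Gm4951 (log2 1.18), Relt (0.68), a TNF receptor family member, Nr6a1 (2.15) and Itprip (0.83), with adjusted p from 0.456 to 0.922 by edgeR. With lower means were Tmem26 (log2 -2.27), the inflammatory cytokine gene Tnf (-1.46, from 3.65 ± 0.67 to 1.32 ± 0.52 CPM), Gm5086 (-0.38), Gm29395 (-1.01) and Rufy2 (-0.45), with adjusted p from 0.546 to 0.999 by edgeR. Among the 8244 genes with a mean of at least 10 CPM, the median absolute log2 fold change was 0.07, its 95th percentile 0.25, and the median 95% confidence interval reached 0.23 to either side. DESeq2 called 11 genes, the 3 above and Sdc3, Gm4951, Relt, Nr6a1, Itprip, Tmem26, Tnf and Gm5086. In simulated data of the same depth 18.9% of its calls were false. Those data were drawn with edgeR's own estimates of the spread and with many changes put in. The share therefore does not say how many of the real DESeq2 calls are false.

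**Figure D2:**
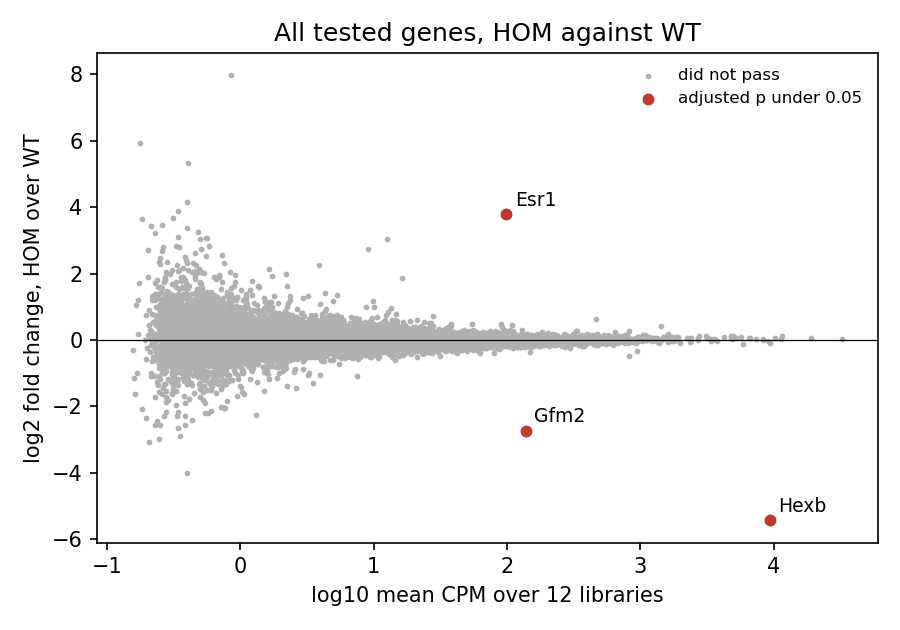
Log2 fold change of HOM over WT (vertical axis) against the log10 of the mean CPM over 12 libraries (horizontal axis) for the 14641 tested genes; red points passed an edgeR adjusted p of 0.05 and grey points did not. Hexb at -5.43, Gfm2 at -2.72 and Esr1 at 3.78 stand apart from the rest.

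Genes that mark resting microglia differed by at most 0.15 on the log2 scale. Of 25 homeostatic microglia genes, 20 were higher and 5 lower in HOM, with a median log2 fold change of 0.05 and values from -0.04 to 0.15. Cst3 differed by 0.02 (SE 0.07) and Csf1r by 0.05 (SE 0.04). P2ry12 (-0.04, SE 0.05) and Tmem119 (0.05, SE 0.06) are genes by which microglia are told from other macrophages. These genes and Cx3cr1 (0.03, SE 0.05) were named after their values were seen. The list had an adjusted p of 0.0791 by camera (adjusted p = 0.205 with an estimated correlation). That value became 0.0212 without WT 3, 0.0216 with library size only and 0.00998 without a low-count filter, each in the upward direction. Over 20 alternatives it ran from 0.00998 to 0.450.

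Lysosomal hydrolases and cofactors, the enzymes that work beside beta-hexosaminidase, were higher in HOM for all 29 of 29 tested members under TMM, RLE and library-size scaling, by a median of 0.07 on the log2 scale with TMM and RLE and 0.09 with library size. Ctsd stood at 11084 ± 532 CPM in WT and 11961 ± 651 CPM in HOM (log2 0.11, SE 0.05) and the protease Ctss at 8186 ± 219 and 8244 ± 403 CPM (log2 0.01, SE 0.04). Hexa, the alpha subunit of the same enzyme (1575 ± 52.3 and 1648 ± 73.4 CPM), and Gm2a, its activator protein, both named after their values were seen, differed by 0.06 (SE 0.05) and 0.05 (SE 0.06). The list rose with an adjusted p of 1.63e-05 by camera (adjusted p = 0.0886 with an estimated correlation) and an adjusted p of 0.00838 by fry. Mean log2 CPM over the list was 8.94 ± 0.03 in WT and 9.03 ± 0.03 in HOM, a 1.07-fold difference without overlap (exact two-sided permutation p = 0.0286, 0.317 after adjustment over the lists). No single member passed, and 0 passed when adjusted over the list alone. Lysosomal membrane and acidification genes had 12 of 22 members higher (median 0.00, mean -0.04, adjusted p = 0.902 by camera) and glycosphingolipid synthesis genes 4 of 8 (median 0.00, mean -0.02, adjusted p = 0.956 by camera). Lamp1 and Lamp2, the main lysosomal membrane proteins, differed by 0.05 (SE 0.05) and 0.09 (SE 0.08), and the ganglioside synthases St3gal5 and St3gal2 by -0.06 (SE 0.09) and 0.03 (SE 0.07).

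Interferon-stimulated genes, which encode antiviral proteins, were higher in HOM for 20 of 22 members, by a median of 0.41 on the log2 scale. The list rose with an adjusted p of 2.16e-10 by camera (adjusted p = 0.205 with an estimated correlation). No member passed over all genes, and 4 passed when adjusted over the list alone: Ifit3 (log2 0.57, SE 0.17), Oasl2 (0.79, SE 0.24), Rsad2 (1.07, SE 0.34) and Ifi204 (0.99, SE 0.26), named after their values were seen. Bst2 and Stat1, the members with the highest counts, differed by 0.15 (SE 0.13) and 0.05 (SE 0.11). Mean log2 CPM over the list was 2.82, 3.34, 3.12 and 3.22 in the WT libraries and 3.71, 3.89, 3.09 and 3.74 in the HOM libraries (exact two-sided permutation p = 0.114). Proliferation genes were higher for 16 of 19 members, by a median of 0.36, with list means of 1.45 ± 0.21 in WT and 2.06 ± 0.26 in HOM (exact two-sided permutation p = 0.0286, 0.317 after adjustment over the lists). The proliferation list rose with an adjusted p of 4.18e-05 by camera (adjusted p = 0.15 with an estimated correlation), and 0 of its members passed when adjusted over the list alone. The DNA replication genes Mcm3 and Pcna, its members with the highest counts, differed by 0.16 (SE 0.08) and 0.03 (SE 0.10).

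Disease-associated microglia genes were higher for 22 of 25 members by a median of 0.12, antigen presentation genes for 13 of 16 by 0.15, and sterol synthesis genes for 15 of 18 by 0.16. Ctsb differed by 0.12 (SE 0.05), B2m and H2-D1, which form MHC class I, by 0.06 (SE 0.06) and 0.15 (SE 0.10), and the lipid enzymes Scd2 and Msmo1 by 0.04 (SE 0.12) and 0.09 (SE 0.08). Camera gave adjusted p = 0.000183 for the disease-associated list (adjusted p = 0.22 with an estimated correlation), 0.000281 for antigen presentation (adjusted p = 0.244 with an estimated correlation) and 0.00185 for sterol synthesis (adjusted p = 0.18 with an estimated correlation). Members passing when adjusted over the list alone numbered 0 in all 3. The exact two-sided permutation p of the list means was 0.200, 0.0857 and 0.0571 in the same order. Border-associated macrophage markers, which tell macrophages of the brain's surfaces from microglia, moved with these lists: 10 of 11 were higher, by a median of 0.93 (adjusted p = 1.63e-05 by camera, adjusted p = 0.205 with an estimated correlation). Their library means were 0.11 and 0.42 in WT 1 and WT 2, 1.82 and 2.26 in WT 3 and WT 4, and 2.21 ± 0.82 over the HOM libraries (SD, n = 4). The exact two-sided permutation p of these means was 0.229 for HOM against WT. Mrc1 stood at 42.9 ± 19.0 and 52.8 ± 8.64 CPM and Stab1 at 359 ± 29.0 and 380 ± 64.0 CPM. Without WT 1 and WT 2, an alternative chosen after the data were examined, the adjusted p by camera became 0.519 for disease-associated genes, 0.194 for antigen presentation, 0.170 for sterol synthesis and 0.182 for the macrophage markers. Over 20 alternatives these 4 adjusted p-values ran from 9.33e-09, 2.59e-08, 0.000196 and 3.22e-11 up to 0.519, 0.244, 0.180 and 0.226. Without WT 1 and WT 2 it was 1.23e-09 for interferon-stimulated genes, 0.00145 for lysosomal hydrolases and 0.000154 for proliferation genes, and within library numbers 1 to 7 it was 2.03e-13, 0.000343 and 0.0481.

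Choroid plexus and ependymal markers rose in HOM, with 4 of 4 tested members higher (adjusted p = 0.000266 by camera, adjusted p = 0.205 with an estimated correlation). The exact two-sided permutation p of the list mean was 0.143. Ttr, which encodes the thyroid hormone carrier made by the choroid plexus, stood at 1.73 ± 2.07 CPM in WT and 11.4 ± 12.0 CPM in HOM (log2 2.75, SE 1.21). Ttr, Folr1 and Kl passed when adjusted over the list alone. Kl had no count in any WT library. The remaining lists were not called, and their adjusted p by camera follow. Complement genes had 10 of 10 members higher (median 0.10, adjusted p = 0.0813), and its members with the highest counts, C1qb and C1qc, differed by 0.02 (SE 0.06) and 0.06 (SE 0.07). The complement list passed without WT 2 (0.0492) or HOM 3 (0.0116), with library size only (0.0481), without a low-count filter (0.0223) and within library numbers 1 to 7 (0.0112). Inflammatory cytokine and NF-kB genes had 7 of 16 higher (0.383), with Tnf passing when adjusted over the list alone, immediate early and heat shock genes 9 of 22 (0.422), and unfolded protein and amino acid stress genes 6 of 14 (0.472, median -0.03 and mean 0.06). Ribosomal protein genes had 20 of 78 higher (0.0813), and were lower past the threshold without WT 3 (2.64e-05), HOM 2 (0.0417) or HOM 4 (7.72e-08). Mitochondrially encoded genes had 5 of 7 higher (0.457, and 0.0371 without HOM 3). Among markers of other cells, monocyte and dendritic cell markers had 3 of 6 higher (0.956), lymphocyte markers 2 of 4 (0.683, median 0.03 and mean -0.39), erythroid markers 0 of 4 (0.472, and 9.62e-05 without WT 1 and WT 2), neuron markers 1 of 3 (0.383), astrocyte markers 6 of 9 (0.383), oligodendrocyte lineage markers 3 of 7 (0.422, median -0.00 and mean 0.99), endothelial and mural markers 4 of 7 (0.168) and sex-linked genes 4 of 5 (0.42, and 0.0487 without WT 4). Snap25, one of the neuron markers, passed when adjusted over the list alone (log2 -2.05, 1.42 ± 0.54 CPM in WT). Of the neutrophil markers only Csf3r was tested (log2 0.02, SE 0.07), so that list had no test.

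**Figure D3:**
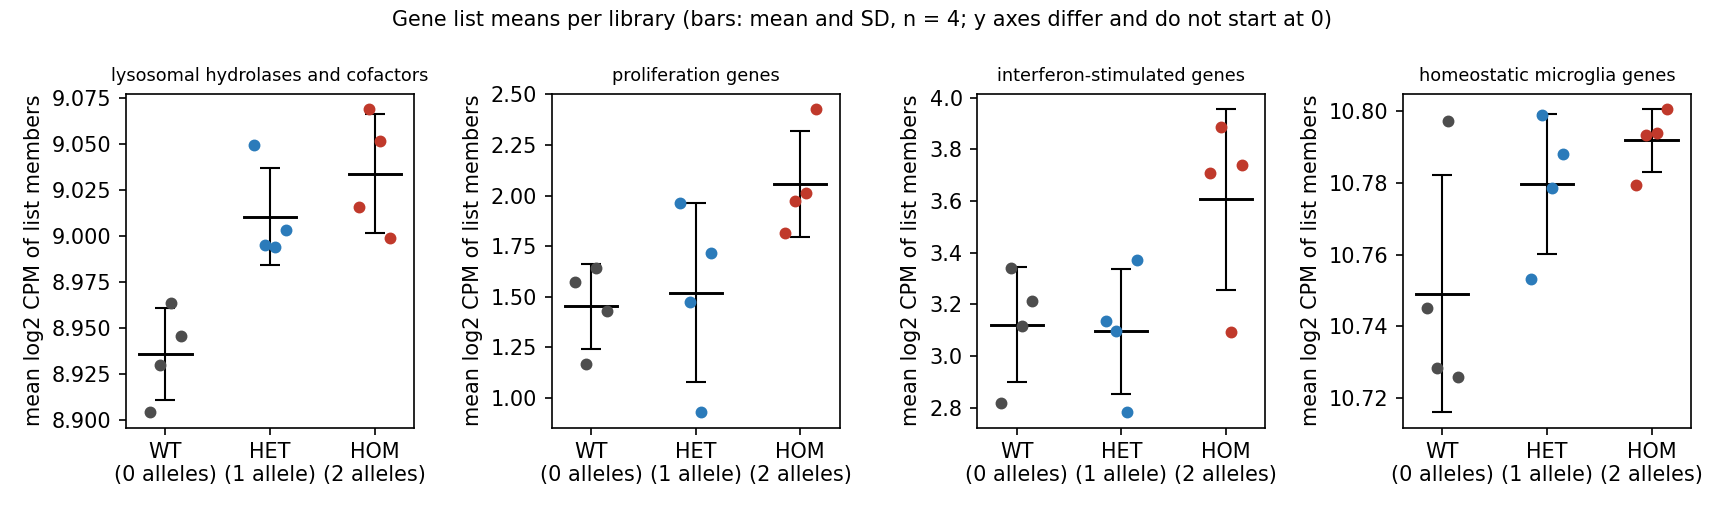
Mean log2 CPM over the tested members of 4 gene lists (vertical axes, which differ and do not start at 0) in each library by genotype (horizontal axis); points are libraries, lines the mean and bars the SD of 4. All HOM libraries lie above all WT libraries for lysosomal hydrolases and for proliferation genes, while the interferon-stimulated list has 1 HOM library, at 3.09, among the WT values.

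HET against WT asks what a single knock-in allele changes in mice that keep the other Hexb allele, the state in which a driver line is commonly used. Hexb fell by 0.91 on the log2 scale (SE 0.10, adjusted p = 0.000815 by edgeR). Gfm2 fell by 0.78, to 139 ± 1.06 CPM (SE 0.07, adjusted p = 3.01e-05 by edgeR), and Esr1 rose by 2.82, to 95.9 ± 6.87 CPM (SE 0.17, adjusted p = 3.22e-07 by edgeR). The exact two-sided permutation p was 0.0286 for each. They were again the 3 genes past the threshold of 14641 tested, with 540 at an unadjusted p under 0.05, while DESeq2 called 7. In library numbers 8 to 12, which hold 1 WT library assumed to vary like the others, Hexb differed by -0.90 and Gfm2 by -0.83 with adjusted p = 0.929 for both by edgeR, and in library numbers 1 to 7 by -0.92 and -0.76 with adjusted p = 0.02. Esr1 differed by 3.07 and 2.72 in the same sets.

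Outside Hexb, Gfm2 and Esr1, the smallest adjusted p in HET against WT was 0.281 by edgeR, for a gene with a mean below 1 CPM. Among genes of at least 1 CPM that did not pass, those with the smallest p and higher means were Itprip (log2 0.86, SE 0.20), Smpd3 (2.29), a neutral sphingomyelinase gene, Slc5a5 (1.49), the galectin gene Lgals3 (0.97, from 3.32 ± 1.24 to 6.49 ± 1.49 CPM) and Ildr2 (1.05), all with adjusted p = 0.995 by edgeR. Lower means were seen for Rad51ap1 (log2 -1.69, adjusted p = 0.884 by edgeR) and, at adjusted p = 0.995 by edgeR, for Gm20696 (-0.66), Fbxl18 (-0.56), 9630010A21Rik (-1.20) and C130089K02Rik (-0.70).

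Disease-associated microglia genes rose in HET as a list, with 23 of 25 members higher by a median of 0.12 (adjusted p = 1.39e-05 by camera, adjusted p = 0.374 with an estimated correlation), and Lgals3 passed when adjusted over the list alone. Lysosomal hydrolases rose as a list, with 28 of 29 members higher by a median of 0.06 and 0 passing when adjusted over the list alone (adjusted p = 0.000856 by camera, adjusted p = 0.178 with an estimated correlation), with list means of 8.94 ± 0.03 in WT and 9.01 ± 0.03 in HET (exact two-sided permutation p = 0.0286, 0.476 after adjustment over the lists). Antigen presentation genes (11 of 16 higher) and inflammatory cytokine and NF-kB genes (10 of 16 higher) both had an adjusted p of 0.0356 by camera (adjusted p = 0.595 and adjusted p = 0.399 with an estimated correlation). Ribosomal protein genes were lower for 71 of 78 members by a median of -0.08 (adjusted p = 2.40e-05 by camera, adjusted p = 0.635 with an estimated correlation). Border-associated macrophage markers rose with these lists, with 9 of 11 higher by a median of 0.17 (adjusted p = 0.00103 by camera, adjusted p = 0.399 with an estimated correlation), as did erythroid markers, with 4 of 4 higher (adjusted p = 0.00219 by camera, adjusted p = 0.374 with an estimated correlation). Erythroid list means were -2.26 and -2.75 in WT 1 and WT 2 and 0.22 to 2.51 in HET, and Hbb-bt passed when adjusted over the list alone. The exact two-sided permutation p of the list means was 0.143 for disease-associated, 0.114 for antigen presentation, 0.143 for inflammatory and 0.486 for ribosomal protein genes. It was 0.257 for macrophage and 0.143 for erythroid markers, and HET and WT libraries overlapped in each of these lists. Without WT 1 and WT 2, camera gave adjusted p of 0.486 for disease-associated genes, 0.0634 for lysosomal hydrolases, 0.822 for antigen presentation, 0.486 for inflammatory genes, 0.562 for ribosomal protein genes, 0.742 for macrophage markers and 0.575 for erythroid markers. The antigen presentation and inflammatory calls also ended without single libraries: WT 1 (0.131 and 0.0992), WT 2 (0.219 and 0.0689), WT 3 (0.0656 and 0.111), HET 1 (0.0616 and 0.1005) or HET 4 (0.685 and 0.274), and the ribosomal call ended without HET 3 (0.803). Over 20 alternatives the adjusted p ran from 7.65e-11 to 0.486 for disease-associated genes, from 1.64e-05 to 0.178 for lysosomal hydrolases and from 2.96e-10 to 0.882 for ribosomal protein genes.

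Choroid plexus and ependymal markers rose in HET with 4 of 4 tested members higher (adjusted p = 4.87e-06 by camera, adjusted p = 0.178 with an estimated correlation; 3.63e-08 without WT 1 and WT 2). Ttr stood at 14.2 ± 10.8 CPM in HET (log2 3.07, SE 1.22), and Ttr, Folr1 and Kl passed when adjusted over the list alone. The exact two-sided permutation p of the choroid plexus list mean was 0.0571. Interferon-stimulated genes had 7 of 22 members higher and 15 lower (median -0.06, adjusted p = 0.197 by camera, 0.00256 without WT 1 and 0.0194 without HET 4, in the downward direction). Homeostatic microglia genes had 15 of 25 higher (median 0.02, adjusted p = 0.169 by camera) and proliferation genes 13 of 19 (median 0.06, adjusted p = 0.186 by camera, 0.0134 without HET 3). The other 14 tested lists had adjusted p from 0.084 to 0.945 by camera. Mitochondrially encoded genes passed without WT 2 (0.00412), WT 4 (0.0194) or HET 4 (0.00378), sterol synthesis genes without WT 4 (0.0253) or HET 2 (0.0439), sex-linked genes without WT 4 (0.0283) and endothelial markers without HET 4 (0.0194), each upward. Median and mean differed in sign for lysosomal membrane genes (0.02 and -0.00), glycosphingolipid synthesis genes (0.01 and -0.02), complement genes (0.05 and -0.04) and astrocyte markers (-0.03 and 0.25), with the test upward in all 4.

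HOM against HET asks what losing the second Hexb allele adds. Hexb fell by 4.52 on the log2 scale (SE 0.12, adjusted p = 4.99e-13 by edgeR) and Gfm2 by 1.94 (SE 0.07, adjusted p = 4.81e-11 by edgeR). Esr1 was at 95.9 ± 6.87 CPM in HET and 187 ± 27.5 CPM in HOM, with an exact two-sided permutation p of 0.0286 and a log2 fold change of 0.97 (SE 0.16) whose adjusted p of 0.0577 by edgeR did not pass. Esr1 passed in 10 of 25 alternatives, among them limma-voom (adjusted p = 0.00146), library size only (0.0421 by edgeR) and fits without WT 1 (0.0483) or WT 2 (0.00374). Its adjusted p ran from 1.58e-07 to 0.908. The third gene past the threshold was Gm20696 (chromosome 6, 99257484 to 99666797, minus strand), a predicted gene at 4.80 ± 0.73 CPM in HET and 9.52 ± 0.88 CPM in HOM (log2 0.99, SE 0.15, adjusted p = 0.0427 by edgeR), which rose. Its WT libraries stood at 7.58 ± 0.15 CPM. Gm20696 shares its position and strand with the transcription factor gene Foxp1 and with Eif4e3, which differed by 0.13 (SE 0.10) and 0.04 (SE 0.11), so its counts are uncertain.

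The count of changed genes in HOM against HET was 3, with 553 genes at an unadjusted p under 0.05, while DESeq2 called 11. Within library numbers 1 to 7 and 8 to 12, Hexb differed by -4.47 and -4.57, Gfm2 by -1.98 and -1.91 and Esr1 by 0.95 and 0.98. The Gm20696 call ended without any one of the HET libraries (adjusted p by edgeR of 0.198, 0.185, 0.127 and 0.0635 for HET 1 to 4), any one of the HOM libraries (0.240, 0.159, 0.124 and 0.0740 for HOM 1 to 4), WT 3 (0.0628) or WT 4 (0.0795). It also ended with sex-linked expression (0.0745) or the library number (0.0707) as a covariate. Its adjusted p ran from 1.56e-06 to 1 over 25 alternatives. Genes that did not pass included Irf7, a regulator of the interferon response (log2 0.92, SE 0.20, adjusted p = 0.449 by edgeR), the MHC class I regulator Nlrc5 (1.27, adjusted p = 0.423 by edgeR), Gm37465 (1.75) and C130089K02Rik (0.86). Lower means in HOM were seen for Rims3 (-1.29), Acad11 (-0.45), Tnf (-1.12), Rfx5 (-0.47) and Tmem65 (-0.31), at unadjusted p from 0.00213 to 0.003 and adjusted p above 0.999 by edgeR.

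Interferon-stimulated genes rose in HOM over HET as a list, with 21 of 22 members higher by a median of 0.60 on the log2 scale (adjusted p = 7.74e-17 by camera, adjusted p = 0.246 with an estimated correlation). When adjusted over the list alone 11 members passed, among them Irf7, Rtp4 (0.64, SE 0.15), Oasl2 (0.84, SE 0.24) and Ifitm3 (0.62, SE 0.23), the last 3 named after their values were seen. List means were 3.13, 3.10, 2.78 and 3.37 in the HET libraries, against 3.71, 3.89, 3.09 and 3.74 in HOM (exact two-sided permutation p = 0.114). Inflammatory cytokine and NF-kB genes fell, with 12 of 16 lower by a median of -0.26 (adjusted p = 0.00131 by camera, adjusted p = 0.246 with an estimated correlation), and Tnf and the chemokine gene Ccl2 (6.52 ± 0.35 CPM in HET, 3.97 ± 0.73 in HOM) passed when adjusted over the list alone. Proliferation genes rose, with 14 of 19 higher by a median of 0.15 (adjusted p = 0.0115 by camera, adjusted p = 0.35 with an estimated correlation). Erythroid markers fell, with 4 of 4 lower by a median of -2.06 (adjusted p = 0.000447 by camera, adjusted p = 0.246 with an estimated correlation). The haemoglobin gene Hbb-bs was at 13.5 ± 5.15 CPM in HET and 2.95 ± 3.69 CPM in HOM, and Hbb-bt passed when adjusted over the list alone. The exact two-sided permutation p was 0.0571 for the inflammatory, the proliferation and the erythroid list means alike. Without HOM 4 the inflammatory call ended (0.0929) and so did the proliferation call (0.199), which also ended without HET 3 (0.461) and within library numbers 1 to 7 (0.798).

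The lists not called in HOM against HET included lysosomal hydrolases, with 18 of 29 higher (median 0.02, adjusted p = 0.479 by camera), or 26 of 29 when scaled by library size alone. Homeostatic microglia genes had 18 of 25 higher (0.867) and disease-associated genes 12 of 25 (0.893). Border-associated macrophage markers had 10 of 11 higher (0.448) and ribosomal protein genes 64 of 78 (0.0888). Ribosomal protein genes passed by camera without HET 1 (0.000134), HET 2 (0.0336), HET 4 (0.0193), HOM 1 (2.48e-06) or HOM 3 (0.00422), antigen presentation genes without HET 4 (0.0137), upward. Choroid plexus markers passed without HET 1 (0.0494), downward. Median and mean differed in sign for unfolded protein genes (-0.03 and 0.07), lymphocyte markers (0.05 and -0.56), neuron markers (0.00 and -0.08) and oligodendrocyte lineage markers (-0.01 and 0.23). The complement gene C3 and the endothelial marker Ly6a were higher, and the natural killer cell marker Klrb1c lower, when adjusted over the list alone.

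Across the 3 genotypes, Hexb, Gfm2 and Esr1 changed with the number of alleles in near-equal steps on the linear scale. The HET mean lay 401 CPM (SE 243) from the midpoint of WT and HOM for Hexb, 1.63 CPM (SE 2.78) for Gfm2 and -4.53 CPM (SE 7.75) for Esr1. The change in HOM was 2.10 (SE 0.06), 2.03 (SE 0.06) and 2.11 (SE 0.19) times the change in HET. On the log2 scale the slope per allele was -2.71 for Hexb (SE 0.37, adjusted p = 0.00553 by edgeR), -1.36 for Gfm2 (SE 0.10, adjusted p = 1.71e-06) and 1.86 for Esr1 (SE 0.18, adjusted p = 6.51e-05), and no other of the 14641 genes passed, with 549 at an unadjusted p under 0.05 and 9 called by DESeq2. The Hexb slope did not pass without HOM 1 (-2.56, adjusted p = 0.0624 by edgeR). The departure of Hexb from a straight line on that scale was -3.62 (SE 0.17, adjusted p = 5.39e-09 by edgeR), since equal linear steps towards 0 bend on a log scale.

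Gfm2 (chromosome 13, 97137937 to 97181195, plus strand) overlaps Hexb over 4865 bases, from 97176331 to 97181195. Of these, 615 bases are exonic in both genes, which is 32.3% of the 1906 exonic bases of Hexb, and a further 2709 exonic bases of Gfm2 lie inside Hexb introns. The kit does not mark strand, so reads of Hexb and Gfm2 in the shared stretch cannot be separated in these counts. Within 5 Mb of Hexb, 74 other genes were tested and Gfm2 was the 1 called in each of the 3 comparisons (Fisher exact two-sided p = 0.0101 in each). Without Gfm2, 0 of 73 were called by edgeR. In HOM over WT 40 of the 73 were higher (median log2 fold change 0.03), as were 13 of the 25 within 2 Mb (median 0.07). The nearest genes besides Gfm2 had log2 fold changes in HOM over WT of 0.71 (SE 0.50) for Fam169a, -0.44 (SE 0.15) for Nsa2, -0.50 (SE 0.17) for Enc1, -0.38 (SE 0.08) for Gm5086 and -0.21 (SE 0.11) for Utp15. In HET over WT they were 0.65, -0.25, -0.40, -0.20 and 0.09 in the same order. None of the 5 passed edgeR's adjustment in either comparison. As a set they had an adjusted p by fry of 0.00179 in HOM over WT (4 of 5 lower), 0.0697 in HET over WT (3 of 5 lower) and 0.0180 in HOM over HET (4 of 5 lower). Their mean log2 CPM was 3.65 ± 0.11 in WT, 3.60 ± 0.13 in HET and 3.45 ± 0.15 in HOM (SD, n = 4), with an exact two-sided permutation p of 0.0571 for HOM against WT, 0.571 for HET against WT and 0.200 for HOM against HET (0.171, 0.571 and 0.300 after adjustment over the 3). Both tests of the set were chosen after the values were seen.

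**Figure D4:**
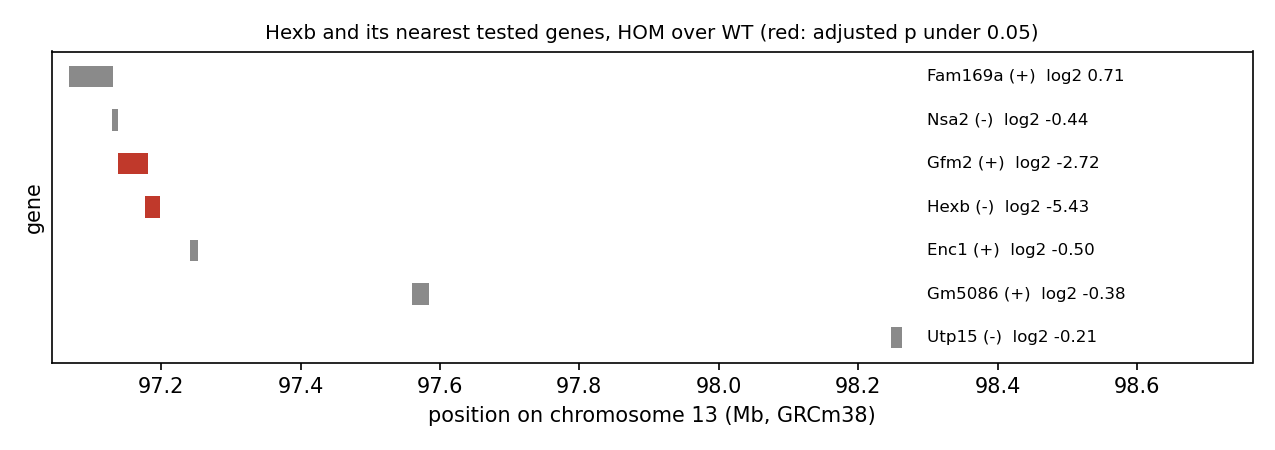
Position of Hexb and its nearest tested genes on chromosome 13 (horizontal axis, Mb, GRCm38), 1 gene per line, with strand and log2 fold change of HOM over WT; red genes passed edgeR's adjusted p of 0.05. Gfm2 and Hexb overlap and are the 2 red genes, at -2.72 and -5.43, while the other 5 lie between -0.50 and 0.71.

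Over all genes, the fold changes of HOM against WT and of HET against WT were compared with what sharing WT libraries alone gave in simulated data. Without Hexb, Gfm2 and Esr1, their correlation across genes, which are not independent replicates, was 0.558. In 20 simulations of unchanged groups with shared WT libraries, the mean correlation was 0.505 (0.471 to 0.537). Simulated genes varied independently of each other, while genes of the real libraries can vary together. The simulated range may therefore be too narrow, and a correlation above it does not show a shared effect of the knock-in. The observed covariance was 0.0901, 0.0129 above the simulated 0.0773. Among genes with at least 10 CPM the observed covariance was 0.00983, a difference of -0.00266 from the simulated 0.0125. With the WT libraries split into separate pairs for each comparison, the mean correlation over 6 assignments was 0.0539. The overlap of called genes was 3, namely Hexb, Gfm2 and Esr1, where independent lists would share 0.000273 falling and 6.83e-05 rising genes. Without these 3 genes the overlap was 0, the same as in the simulations, which were counted without them.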

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

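The comparison of Gfm2 with its neighbours and the set tests of these, the midpoint tests of Gfm2 and of interferon-stimulated genes, the Esr1 ratio and all 4 counts of other splits were chosen after the result was seen, while the slopes within genotypes and the 2 covariate tests were set out before.

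For Gfm2, which fell with each knock-in allele and overlaps Hexb, a fall of that size over the whole neighbourhood is argued against, because the 5 other nearest tested genes had a median log2 fold change of -0.38 in HOM over WT, short of -1.36, which is 0.5 times the Gfm2 value, and without Gfm2 40 of 73 genes within 5 Mb and 13 of 25 within 2 Mb were higher. A smaller fall of the nearest genes alone stays open, as 4 of the 5 were lower, with an adjusted p of 0.00179 by fry and an exact two-sided permutation p of 0.0571 for their mean (0.171 adjusted over the 3 comparisons). Hexb reads counted as Gfm2 through the overlap may be the source: within genotypes Gfm2 gained 0.00947 CPM per Hexb CPM (95% interval -0.000304 to 0.0192), and between genotypes the slope was 0.0116. Less transcription of Gfm2 itself, set by the number of knock-in alleles, may be the source as well, and the HET mean lay 1.63 CPM from the midpoint (SE 2.78). These last 2 cannot be told apart, since the allele number sets Hexb and Gfm2 alike and the counts carry no strand.

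Esr1 rose with each allele although its gene lies on another chromosome. A candidate explanation is reads of the oestrogen receptor domain of CreERT2 counted as Esr1, and the HOM rise was 2.11 times the HET rise (SE 0.19), where 2 copies against 1 predict 2. A response of the endogenous gene to the level of Hexb cannot be told apart from this, because the slope within genotypes was 7.77 CPM of Esr1 per kilo-CPM of Hexb with a 95% interval of -24.1 to 39.7, which holds both 0 and the slope between genotypes of -9.90. Mapping the reads to the cassette sequence would separate the pair, and reads were not used here.

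Interferon-stimulated genes were higher in HOM than in HET by 0.51 (log2) in list mean, with an exact two-sided permutation p of 0.114. RNA of border-associated macrophages, set against the marker list fixed beforehand (Mrc1 at 47.6 and Stab1 at 368 CPM in HET), is argued against as the whole source, since with the macrophage mean as covariate the difference was 0.49 (95% interval 0.03 to 0.96). A steady trend with library order could add little, because library numbers are spread alike over HET and HOM. With the library number as a covariate the difference was therefore bound to stay near its value, at 0.51 (0.03 to 0.99). Other effects of library order were not tested. A graded response to the number of alleles stays open, as the HET mean lay -0.27 from the midpoint (SE 0.16) and -0.03 from WT (SE 0.16). A response to the loss of both alleles may also be at work and is a hypothesis only, since the exact test did not pass and 1 HOM library stood at 3.09.

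Each count of 3 changed genes was set against all other splits of the same 8 libraries or, per allele, against random relabellings. For HOM against WT, 1 of 35 splits gave as many genes, which was the real one, and the highest other gave 2. For HET against WT it was 1 of 35 with a highest other of 1, and per allele 1 of 100 with a highest other of 2. Hexb, which carries the cassette, is among the 3 genes of each count, and a split that mixes genotypes tends to lose it. These counts therefore say little about chance beyond the knock-in itself. For HOM against HET, 2 of 35 splits gave as many, with a highest other of 3, so chance is not excluded by the count. That other split put HET 1, HET 2, HOM 1 and HOM 2 against the rest, which is the split by sex-linked transcripts and library order. With sex-linked expression as a covariate, HOM against HET gave 2 genes, Hexb and Gfm2.

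In 12 of 177 groups of 4 libraries, 1 library stood far from the other 3, and chance alone gives about 1 in 20 groups, or 8.85. Among the WT libraries, total counts stood apart in WT 3, at 35.4 M. Among named genes the libraries standing apart were HOM 1 for Ildr2 (4.99 CPM, highest), HOM 3 for Irf7 (8.57 CPM, lowest), WT 2 for Rims3 (3.72 CPM, highest), WT 3 for Sdc3 (105.1 CPM, highest), HET 1 for Tmem65 (100.1 CPM, highest) and HOM 3 for Utp15 (51.0 CPM, highest). Among list means in log2 CPM they were HET 1 for lysosomal hydrolases (9.05, highest), HET 1 for astrocyte markers (-0.34, lowest), HOM 2 for astrocyte markers (0.67, highest), WT 4 for endothelial and mural markers (0.50, lowest) and WT 4 for sex-linked genes (3.31, highest).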

How the results depend on the processing

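The fits without WT 1 and WT 2 and within library numbers 1 to 7 or 8 to 12, the neighbour tests without Gfm2, and the fold-change correlation without Hexb, Gfm2 and Esr1 were chosen after the result was seen. Over 25 alternatives the log2 fold change of Hexb ranged from -5.52 to -5.32 in HOM over WT, from -0.94 to -0.88 in HET over WT and from -4.61 to -4.42 in HOM over HET, and it passed in all but 1: within library numbers 8 to 12, with a lone WT library assumed to vary like the others, HET over WT was -0.90 (adjusted p = 0.929 by edgeR), where fewer samples were fitted. The Hexb slope per allele did not pass with robust edgeR (-2.71), in library numbers 1 to 7 (-2.49) or in 8 to 12 (-3.24), and without single libraries it ran from -2.91 to -2.48. Counts of changed genes in HOM over WT, HET over WT and HOM over HET were 5, 10 and 14 without a low-count filter and 11, 7 and 11 with DESeq2, which gave 9 per allele. Library numbers 1 to 7 gave 5 in HOM over WT, and 8 to 12 gave 1 in HET over WT and 1 per allele. Leaving out single libraries gave 2 to 4 genes in HOM over HET and per allele. Without Gfm2 the neighbour p was 1 in the 3 comparisons, since Gfm2 was the only neighbour called. Of the 20 called lists, 20 did not pass with an estimated correlation, 19 with fry and 11 without WT 1 and WT 2. Directions turned in library numbers 1 to 7 for ribosomal protein genes in HET over WT (adjusted p = 0.882 by camera) and HOM over HET (0.000202) and for choroid plexus markers in HOM over HET (0.0449). Where not stated, the cause was not tested. Of 5032 alternative values of named genes, 36 gained and 18 lost a call and 4978 kept their side of the threshold, 321 of which, passing in neither setting, changed sign. Esr1 in HOM over HET (0.88 to 1.03) passed in 10 of 25 alternatives and Gm20696 (0.72 to 1.27) did not pass in 16 of 25. No paired analysis was possible because the replicate numbers follow accession order only. What separates replicates is not stated in the labels. Each genotype holds both Xist and Y-linked libraries, and so more than 1 mouse, but part of the spread behind the p-values may be technical. In simulated data at these library sizes 52.0% of genes changed by 1.5-fold were found, against 76.5% of those with at least 10 CPM, and other depths were not simulated.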

Other observations

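The contrast between library numbers 1 to 7 and 8 to 12, and the choice of marker lists given per library, were made after the result was seen.

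Adjusting for genotype, 7 genes differed by edgeR between library numbers 8 to 12 and 1 to 7, all on the X or Y chromosome, and 0 on other chromosomes. The first principal component of log2 CPM nonetheless separated these sets without overlap. Kdm5d, Ddx3y, Eif2s3y and Uty were higher in numbers 8 to 12. Xist and its antisense partner Tsix were lower, as was Kdm6a, an X-linked histone demethylase gene that escapes X inactivation (82.7 CPM in numbers 1 to 7 and 49.7 CPM in 8 to 12, log2 -0.73, SE 0.10, adjusted p = 0.00629 by edgeR). These genes were named after their values were seen. The genotype difference itself was tested between the 2 sets of libraries: 0 genes passed by edgeR in each of the 3 comparisons, with 459, 352 and 486 at an unadjusted p under 0.05 for HOM over WT, HET over WT and HOM over HET. In the first 2 of these, numbers 8 to 12 hold a single WT library, so the count of 0 says little there.

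Markers of blood and choroid plexus differed between libraries of the same genotype. Erythroid list means in log2 CPM were -2.26, -2.75, 1.08 and 0.62 in WT, 0.96, 2.51, 1.72 and 0.22 in HET and -2.67, -0.62, -1.77 and 0.76 in HOM. Choroid plexus list means were -2.61, -1.29, -3.56 and -3.75 in WT, -2.60, 0.58, 1.37 and 0.79 in HET and 1.51, 0.26, -1.56 and -3.10 in HOM. Homeostatic microglia list means lay between 10.73 and 10.80 in the 12 libraries.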
